A study of Homo sapiens with 8 samples.

How the data were processed

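RNA from MCF7 cells, a luminal breast cancer cell line, and from a PKM2 knockout line derived from them was measured on 8 Human Transcriptome Arrays. Cells were kept at 21% or 1% oxygen for 24 h, and 2 arrays were made per line and oxygen level. The sample titles call the parental arrays WT BBS_MCF7 and the knockout arrays BBS Mut_MCF7. The labels do not explain BBS, or how a BBS mutant relates to the PKM2 knockout. The labels do not say how the knockout line was made or whether it is a single clone, so a line difference is not tied to the loss of PKM2. The labels call the 2 arrays of a group biological replicates. Per the labels' protocols, RNA was extracted with TRIzol and a column kit, and 100 ng was used to make biotinylated cDNA.

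The authors deposited 1 table of log2 values with 67528 rows and 8 arrays, in which values run from 2.32 to 19.93. Per the submitters' processing notes, the raw files were processed with Transcriptome Analysis Console 4.0 against the genome build hg19. The background correction and normalization behind the deposited log2 values are not given in the sources used here. Array medians ran from 4.07 to 4.30, a spread of 0.23, below the limit of 0.5 set for further normalization, so the values were used as deposited. The 4 arrays at 1% oxygen had higher medians (4.19 to 4.30, against 4.07 to 4.11 at 21%) and a narrower spread (SD 2.10 to 2.15, against 2.21 to 2.26). Arrays have no read depth, so the number of arrays limits the precision. With 2 arrays per group, the SD of the difference between replicates over genes was 0.16 and 0.23 for parental cells at 21% and 1% oxygen, and 0.15 and 0.26 for the knockout line.

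Rows were named through the platform annotation given with the table. It pairs 23781 rows with exactly 1 symbol, 1543 rows with several and 42204 with none, and a row without a symbol is unnamed here. Symbols were updated for 251 genes through a RefSeq gene table of assembly GRCh38, which differs from the authors' build and was used otherwise only for gene order. For the 528 genes with more than 1 row, the row with the highest mean over all arrays was kept. This left 22411 genes, 17151 of them protein-coding. The value of a gene is a gene-level signal, so isoforms cannot be told apart. Members of multi-copy families such as the histones may share probes, and their values are uncertain.

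Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on 4 group means, with the spread pooled over all 8 arrays and no replicate block. Tests are two-sided, and p-values were adjusted by Benjamini-Hochberg over the 22411 genes, with a threshold of 0.05. A change is given on the log2 scale with its standard error. The 5 comparisons were the response to 1% oxygen in each line, the knockout line against parental cells at each oxygen level, and the interaction, which is the response of the knockout line minus that of parental cells. Genes are said to have risen, fallen or differed only where the adjusted p was below 0.05.

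Gene lists were tested with camera at a preset correlation of 0.01, against all other genes, with Benjamini-Hochberg adjustment over the 16 lists within a comparison. An estimated correlation was an alternative. Lists were also run with fry, which asks another question, whether a list changed at all, and not whether it moved against other genes. The 16 lists were HIF targets outside glycolysis, glycolysis and lactate export, the PFKFB family with TIGAR, HIF subunits and oxygen sensors, and genes often assigned to HIF-2. Further lists held pentose phosphate and serine synthesis, the TCA cycle and respiratory chain, the cell cycle, the estrogen response, epithelial junctions and keratins, and mesenchymal and basal markers. The last 5 held unfolded protein and amino acid stress, cholesterol synthesis, interferon-stimulated genes, p53 targets, and splicing factors and binding proteins of the PKM exons. The latter list also holds MYC and NEK2. Of 263 list genes, 232 had a row of their own, and the other 31, CA9 among them, have no value here. The overlap of the oxygen responses was tested with Fisher's exact test, one-sided; these 2 comparisons share no arrays.

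The tests, lists and the rule for named genes were fixed before the data were examined. Named in every comparison were PKM, HIF1A, EPAS1, PFKFB1, PFKFB2, PFKFB3, PFKFB4, VEGFA and SLC2A1. The 8 largest rises and the 8 largest falls among called genes were added, where both arrays of one group lay above both of the other (for the interaction, past the threshold only). Up to 4 members with the lowest p were added for each list described. Uncharacterised loci, antisense and small RNA symbols were not named.

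The alternatives were a replicate block, a fit of only the 2 groups compared, leaving out genes below the median level of 4.71, quantile normalization, median centring, all rows of the table, a mean-variance trend with a robust prior, stricter fold thresholds of 2, and leaving out each array in turn. Median centring used the array medians of all 67528 rows, not of the 22411 genes. Cyclic loess normalization was added after the narrower signal range of the arrays at 1% oxygen had been seen. The fit was tested on simulated data for 22411 genes with 50 genes changed per size. For the parental response it recovered 34% of changes of 0.5, 86% of changes of 1 and 98% of changes of 2 on the log2 scale. For the interaction these were 4%, 62% and 90%. The simulation gave 168 calls for the parental response and 134 for the interaction, against 6480 and 2226 in the data. With fewer changed genes the adjusted threshold is stricter, so these shares check the fit and do not give the power of the comparisons here. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.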

Results

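Transcript levels were measured on 8 arrays of MCF7 cells, an estrogen receptor positive breast cancer line. Parental cells and a PKM2 knockout line made from them were kept for 24 h at 21% oxygen or at 1% oxygen, with n = 2 arrays in each of the 4 groups. The labels do not say how the knockout line was made or whether it is a single clone. PKM2 is a splice form of pyruvate kinase M, the enzyme of the last step of glycolysis. The series' title names HIF-2α, encoded by EPAS1, and PFKFB3, an enzyme that makes an activator of glycolysis, so both are followed through every comparison. Levels are log2 signals as deposited, given as mean ± SD (n = 2), and changes are log2 differences ± SE from limma.

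PKM, the gene that encodes PKM2, was lower in both knockout groups than in parental cells. Its level was 13.62 ± 0.02 (SD, n = 2) in parental cells at 21% oxygen and 9.83 ± 0.17 (SD, n = 2) in the knockout line, a 13.8-fold difference. At 1% oxygen the levels were 14.14 ± 0.27 (SD, n = 2) and 11.25 ± 0.16 (SD, n = 2), a 7.41-fold difference. The knockout levels still lay above the 95th percentile of their arrays (9.42 to 9.58). The limma adjusted p was 9.05e-06 at 21% oxygen and 2.83e-05 at 1% oxygen. The gene-level row does not separate PKM1 from PKM2, so it checks the labels of the lines and not the loss of one splice form.

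**Figure D1:**
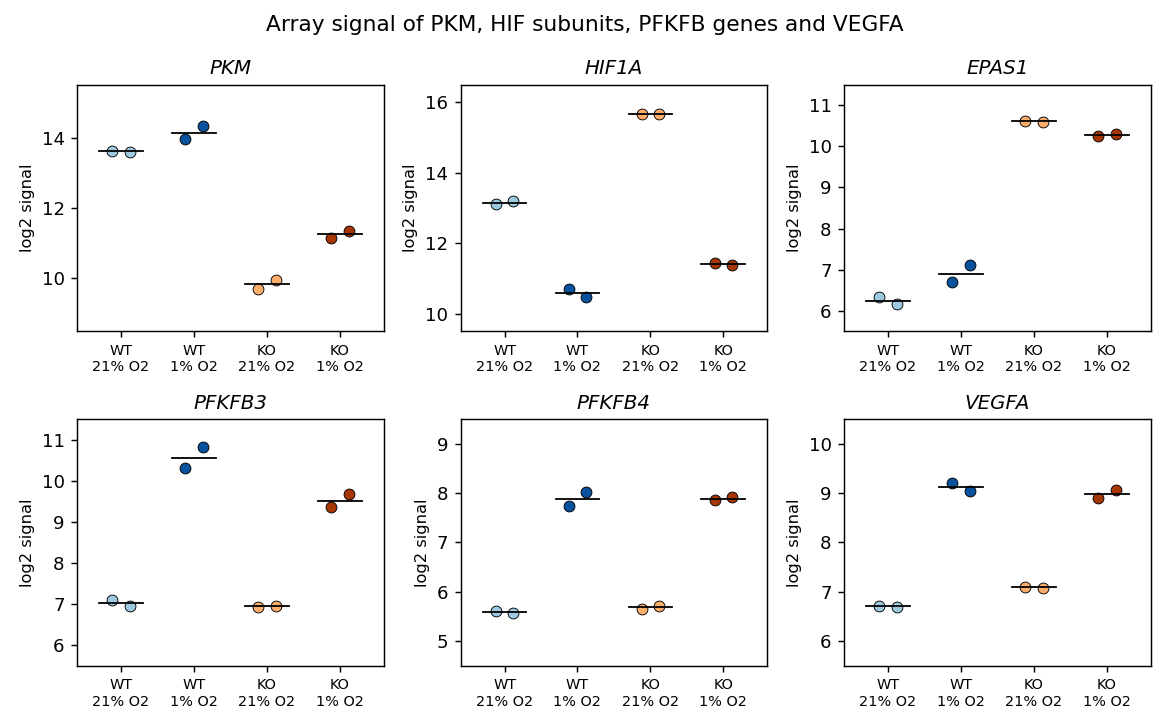
Array signal (log2, y axis) of PKM, HIF1A, EPAS1, PFKFB3, PFKFB4 and VEGFA in parental (WT) and PKM2 knockout (KO) cells at 21% and 1% O2; points are single arrays and lines are means of n = 2. PKM lies at 13.62 in parental cells and 9.83 in knockout cells at 21% O2, while EPAS1 lies at 6.24 and 10.61; the y axes differ and do not start at 0.

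What 24 h at 1% oxygen changed in parental cells was asked first. NDRG1, P4HA1, BNIP3 and KDM3A, from the list of targets of HIF, the transcription factor of the oxygen response, were among the 8 largest rises. NDRG1, a classical hypoxia gene, rose by 6.98 ± 0.11 (127-fold), and P4HA1, a collagen prolyl hydroxylase, by 6.39 ± 0.08 (84.2-fold). ERRFI1, an inhibitor of EGFR signalling, rose by 5.75 ± 0.09, CYP1B1 by 5.72 ± 0.14 and BNIP3, a mitophagy receptor, by 5.68 ± 0.13. ALDOC, POFUT4 and KDM3A, a histone demethylase, rose by 5.5, 5.36 and 5.12. The largest falls were in the histone genes H1-4 (−5.3 ± 0.29), H2BC14 (−4.48 ± 0.17) and H2BC10 (−3.83 ± 0.38), followed by FAM72D (−3.74). These 4 belong to multi-copy families and are uncertain. ANXA9, XBP1, ODC1, the first enzyme of polyamine synthesis, and RHOBTB3 fell, with changes of −3.55, −3.39, −3.3 and −3.29.

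All 25 measured HIF targets outside glycolysis rose in parental cells, also when adjusted over the list alone, with a median of 3.24. The camera adjusted p was 1.8e-25, and 0.028 with an estimated correlation. BHLHE40, a repressor of transcription, rose by 4.96 ± 0.10. Of 20 genes of glycolysis and lactate export, 17 rose and 1 fell, 17 and 1 adjusted over the list alone (adjusted p = 2.7e-10; adjusted p = 0.17 with an estimated correlation). ALDOC, HK2 (4.83 ± 0.14), PGK1 (3.25 ± 0.09) and ENO2 (3.05 ± 0.10) had the lowest p. Of 11 cholesterol synthesis genes 8 rose and 1 fell, with the same counts adjusted over the list alone, among them MSMO1 (2.43 ± 0.10), CYP51A1 (1.36 ± 0.09), STARD4 (1.02 ± 0.10) and HMGCS1 (1 ± 0.07). The adjusted p was 0.00034, or adjusted p = 0.17 with an estimated correlation. VEGFA rose by 2.41 ± 0.09 and the glucose transporter SLC2A1 by 1.88 ± 0.12.

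Other lists fell in parental cells. Of 25 cell cycle genes 23 fell, 25 adjusted over the list alone, with a median of −1.28 (adjusted p = 1.3e-15; adjusted p = 0.2 with an estimated correlation). CCNB1 fell by 2.34 ± 0.10, PLK1 by 2.23 ± 0.11, CCNA2 by 2.07 ± 0.10 and the replication helicase subunit MCM6 by 2.03 ± 0.09. Of 24 genes of the TCA cycle and respiratory chain 21 fell, 22 adjusted over the list alone (adjusted p = 1.8e-10; adjusted p = 0.22 with an estimated correlation). Their median change was −0.67; after quantile normalization it was −0.35 and 12 fell. IDH3A fell by 2.83 ± 0.11, ATP5F1A by 1.54 ± 0.07, NDUFA9 by 1.21 ± 0.08 and IDH3B by 0.92 ± 0.10. Of 15 estrogen response genes 11 fell, 13 adjusted over the list alone (adjusted p = 2.3e-08; adjusted p = 0.2 with an estimated correlation). XBP1, the estrogen receptor gene ESR1 (−2.94 ± 0.13), the progesterone receptor gene PGR (−2 ± 0.11) and NRIP1 (−1.6 ± 0.10) had the lowest p.

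In all, 6480 of 22411 genes changed in parental cells, 2361 up and 4119 down, and 390 rose and 1177 fell over 2-fold. The share of called genes that fell was 63.6% as deposited, 53.5% after quantile normalization, 54% after cyclic loess normalization and 83.5% after median centring, which moved the median change of all genes from 0.065 to −0.085. Without the first or second array of parental cells at 21% oxygen, 4120 and 4075 genes passed.

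The same comparison in the knockout line gave 3588 changed genes, 1427 up and 2161 down; without replicate 1 at 1% oxygen the balance turned, with 2831 up and 1999 down. P4HA1, EGLN3, NDRG1 and ERO1A, from the list of HIF targets, were among the 8 largest rises. ARRDC3 rose by 5.03 ± 0.09, ERRFI1 by 4.83 ± 0.09, P4HA1 by 4.78 ± 0.08, the prolyl hydroxylase EGLN3 by 4.28 ± 0.28 and NDRG1 by 4.23 ± 0.11. ALDOC, IGFBP5 and the oxidoreductase ERO1A rose by 4.21, 4.18 and 4.1. HIF1A had the largest fall, by 4.25 ± 0.10 (19-fold), against a fall by 2.56 ± 0.10 in parental cells. PREX1, PRSS23, H2BC14 and MBOAT1 had changes of −3.23, −3.17, −3.11 and −2.98, and BCAS1, DCDC2 and ODC1 of −2.67, −2.53 and −2.49.

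All 25 measured HIF targets outside glycolysis rose in the knockout line as well, with a median of 2.36. The adjusted p was 5.3e-30, and 0.02 with an estimated correlation; all 25 also passed adjusted over the list alone. BHLHE40 rose by 3.29 ± 0.10 and BNIP3L, a mitophagy receptor, by 2.91 ± 0.10. Of 20 glycolysis and lactate export genes 18 rose and none fell, 19 adjusted over the list alone (adjusted p = 2.6e-16; adjusted p = 0.074 with an estimated correlation). ENO2, PGK1 and PDK1, which restrains pyruvate entry into the TCA cycle, rose by 2.99, 2.39 and 2.05. Of 11 cholesterol synthesis genes 8 rose and 1 fell, 10 and 1 adjusted over the list alone, among them INSIG1 (1.07 ± 0.08), CYP51A1 (0.82 ± 0.09), LSS (0.77 ± 0.08) and STARD4 (0.74 ± 0.10). The adjusted p was 6.2e-06, or adjusted p = 0.074 with an estimated correlation.

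Of 13 genes often assigned to HIF-2, 4 rose and 1 fell in the knockout line, with the same counts adjusted over the list alone (adjusted p = 0.014; adjusted p = 0.18 with an estimated correlation; adjusted p = 0.059 after quantile normalization). Without replicate 1 of the knockout line at 1% oxygen, the adjusted p of this list was 0.082. CITED2 rose by 3.76 ± 0.09, LOXL2 by 2.88 ± 0.12 and the lipid droplet gene PLIN2 by 0.99 ± 0.08, and the iron transporter gene SLC11A2 fell by 0.75 ± 0.08. Of 15 estrogen response genes 10 fell, 11 adjusted over the list alone (adjusted p = 9.2e-12; adjusted p = 0.18 with an estimated correlation), with XBP1 (−2.02 ± 0.14), CA12 (−1.96 ± 0.18), RET (−1.79 ± 0.08) and PDZK1 (−1.7 ± 0.13) among them. Of 25 cell cycle genes 10 fell and 3 rose, 14 and 3 adjusted over the list alone, and the adjusted p was 0.00016, or adjusted p = 0.5 with an estimated correlation. It was 0.057 after quantile normalization and 0.06 without genes below the median level. CCNB1, PLK1, MCM6 and AURKA fell, with changes of −1.61, −1.56, −1.3 and −1.29.

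Over 2-fold, 268 genes rose and 324 fell in the knockout line. The share of called genes that fell was 60.2% as deposited, 41.4% without replicate 1 at 1% oxygen and 81.6% after median centring, which moved the median change of all genes from 0.055 to −0.09. Without the first or second knockout array at 21% oxygen, 1679 and 1694 genes passed, and 2351 passed when only the 2 groups compared were fitted.

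The responses of the 2 lines overlapped. Of the genes that rose, 711 rose in both lines against 150.3 for independent lists, and 1694 fell in both against 397.2. The log10 of the one-sided Fisher's exact p was −339 and −933. That test counts genes as independent, which they are not, so these values overstate the evidence. The arrays at 1% oxygen of both lines share the narrower signal range, which may add to the overlap and was not tested. Across genes, which are not independent replicates, the correlation of the changes was r = 0.68 and rho = 0.54. The 2 comparisons share no arrays. Another 39 genes rose in parental cells and fell in the knockout line, and 53 went the other way. The count that rose in both was 1102 after quantile normalization, 1097 after cyclic loess normalization and 398 after median centring, and the count that fell in both was 2864 after median centring. Without 1 array, the count that rose in both was 471 (parental 21% oxygen, replicate 1), 387 and 379 (knockout 21% oxygen, replicates 1 and 2) or 1101 (knockout 1% oxygen, replicate 1). The count that fell in both was 871 and 891 without knockout replicate 1 or 2 at 21% oxygen.

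**Figure D2:**
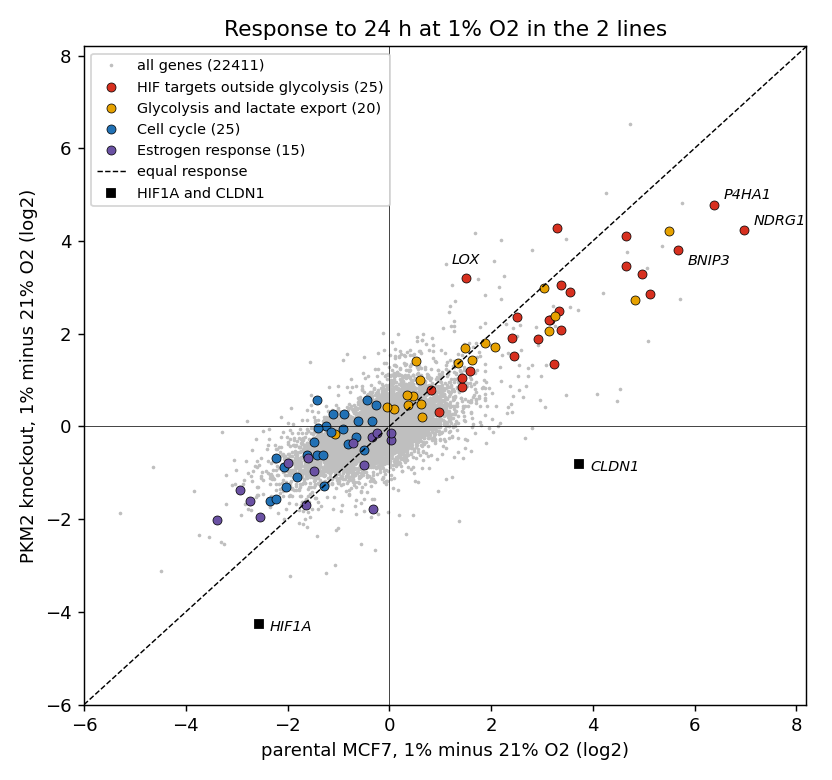
Log2 change after 24 h at 1% O2 in parental cells (x axis) and in the PKM2 knockout line (y axis); each grey point is 1 of 22411 genes, colours mark 4 gene lists, black squares mark HIF1A and CLDN1, and the dashed line marks equal change. Most HIF targets lie below the line, such as NDRG1 at 6.98 and 4.23, while LOX, picked after its values were seen, lies above it at 1.51 and 3.2, and CLDN1 sits at 3.73 and −0.81.

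How the knockout line differed from parental cells at 21% oxygen was compared next. SERPINA3, a secreted protease inhibitor, was 81.3-fold higher in the knockout line (6.34 ± 0.14). PREX1 (4.91 ± 0.19), the stress cytokine GDF15 (4.85 ± 0.30), the lipid peroxide reductase GPX4 (4.68 ± 0.26) and EPAS1 (4.36 ± 0.14, 20.6-fold) followed. HIPK2, LDHB and SH3BGRL were higher by 4.36, 4.07 and 4.06. NPY1R, a neuropeptide Y receptor, was 51.3-fold lower (−5.68 ± 0.08) and the actin-severing gene SCIN 44.9-fold lower (−5.49 ± 0.09). PRKD3, SLC6A14, PLXDC2, ANP32E, PLBD1 and HMCN1 were lower, with differences of −4.61, −4.5, −4.12, −4.12, −4.05 and −3.84. LDHB and SH3BGRL in parental cells (3.89 and 4.59) and HMCN1 in the knockout line (4.40) lay below the median gene (4.71), near background, so the sizes and ranks of these 3 differences are uncertain.

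Of 25 cell cycle genes 21 were lower in the knockout line at 21% oxygen, also adjusted over the list alone, with a median of −0.97 (adjusted p = 3.2e-16; adjusted p = 0.2 with an estimated correlation). CCNA2 (−2.62 ± 0.10), MCM7 (−2.49 ± 0.12), CDC20 (−1.85 ± 0.16) and PLK1 (−1.33 ± 0.11) were among them. Of 11 p53 targets 7 were higher, also adjusted over the list alone (adjusted p = 1.5e-05; adjusted p = 0.14 with an estimated correlation). These included GDF15, TP53INP1 (2.45 ± 0.08), SESN1 (0.94 ± 0.10) and ZMAT3 (0.71 ± 0.09). Of 25 HIF targets outside glycolysis 11 were higher and 1 lower, 15 and 2 adjusted over the list alone (adjusted p = 0.00026; adjusted p = 0.19 with an estimated correlation). STC2 was higher by 3 ± 0.15, PLOD2, a collagen lysyl hydroxylase, by 1.33 ± 0.21, BHLHE40 by 0.87 ± 0.10 and VLDLR by 0.69 ± 0.07.

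The list of splicing factors and binding proteins of the PKM exons holds 9 genes, of which PTBP1, HNRNPA1 and RBM4 had no row of their own. Among the 6 measured genes 5 were lower at 21% oxygen, also adjusted over the list alone (adjusted p = 6e-04; adjusted p = 0.14 with an estimated correlation). The transcription factor gene MYC (−1.68 ± 0.15), the kinase gene NEK2 (−0.93 ± 0.16), HNRNPA2B1 (−0.62 ± 0.07) and SRSF3 (−0.53 ± 0.07) had the lowest p. Among HIF subunits and oxygen sensors, HIF1A was higher by 2.52 ± 0.10 and EPAS1 by 4.36, and their partner ARNT (−1.24 ± 0.13) and VHL (−0.53 ± 0.08), which marks HIF for degradation, were lower. Of these 10 genes 4 were higher and 2 lower, 4 and 3 adjusted over the list alone, and the list did not pass (adjusted p = 0.35). Chromosomal neighbours were compared only for EPAS1, so for ARNT and the others a difference in copy number was not tested. Of 16 mesenchymal and basal markers 3 were higher and 1 lower, with the same counts adjusted over the list alone (adjusted p = 0.38). Fibronectin, FN1, was higher by 2.68 ± 0.08 and CAV1 lower (−1.96 ± 0.07). KRT14 passed with a difference of 0.29 ± 0.07, but its levels of 3.82 and 4.11 lay below the median gene, so it does not show expression of this marker. It lost its call without any one of the 4 arrays compared (adjusted p of 0.0842, 0.155, 0.148 and 0.0815). SNAI2 passed with a difference of 0.49 ± 0.13 at levels of 4.34 and 4.83, also near background, with an adjusted p of 0.0839 after quantile normalization, 0.0669 after median centring and 0.0549 after cyclic loess normalization, and lost its call without any one of the 4 arrays compared.

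At 21% oxygen 4713 genes differed between the lines, 2027 higher and 2686 lower in the knockout line, and 470 and 622 of these over 2-fold. When only the 2 groups compared were fitted, 5915 genes passed. Without replicate 1 or 2 of parental cells 3123 and 3074 genes passed, and without replicate 1 or 2 of the knockout line 3111 and 3046.

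At 1% oxygen the lines were compared again. The histone gene H2BC21 was higher in the knockout line by 4.75 ± 0.22, XBP1 by 4.3 ± 0.14, GDF15 by 4.19 ± 0.30, IGFBP5 by 3.95 ± 0.12 and GPX4 by 3.92 ± 0.26. SLC12A2, TSPYL5 and SH3BGRL were higher by 3.88, 3.87 and 3.79. MT1F, a metallothionein, was 33.9-fold lower (−5.08 ± 0.14), NPY1R 21.1-fold lower (−4.4 ± 0.08) and the collagenase MMP13 15.2-fold lower (−3.92 ± 0.17). PRKD3, SLC6A14, PRKAA2, a catalytic subunit of AMPK, TGFB2 and PLBD1 had differences of −4.07, −4.01, −3.84, −3.79 and −3.78. SH3BGRL in parental cells (4.65) and PRKAA2 in the knockout line (4.76) lay near background, so the sizes and ranks of these 2 differences are uncertain.

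Of 25 HIF targets outside glycolysis 13 were lower and 3 higher in the knockout line at 1% oxygen, 13 and 4 adjusted over the list alone, with a median of −0.26 (−0.4 after quantile normalization). The adjusted p was 0.00023, or adjusted p = 0.32 with an estimated correlation. NDRG1 (−2.26 ± 0.11), BNIP3 (−2 ± 0.13), MXI1 (−1.97 ± 0.13) and KDM3A (−1.87 ± 0.13) were lower. Members of this list also lay the other way, such as EGLN3, with mean levels of 8.58 in parental and 11.15 in knockout cells. Of 20 glycolysis and lactate export genes 7 were lower and 4 higher, 9 and 4 adjusted over the list alone (adjusted p = 0.01; adjusted p = 0.52 with an estimated correlation), and PKM is itself a member. HK2 was lower (−2.1 ± 0.14), as was ALDOC (−1.33 ± 0.10), and PDK3 was higher by 1.38 ± 0.09. That list had an adjusted p of 0.05, not past the threshold, without genes below the median level, and 0.066 without replicate 2 of parental cells at 1% oxygen.

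Of 15 estrogen response genes 9 were higher and 3 lower, with the same counts adjusted over the list alone (adjusted p = 0.0014; adjusted p = 0.52 with an estimated correlation). XBP1, TFF1 (2.95 ± 0.17), NRIP1 (1.68 ± 0.10) and PGR (1.12 ± 0.11) were higher. Of 11 p53 targets 6 were higher, 7 adjusted over the list alone (adjusted p = 0.00096; adjusted p = 0.32 with an estimated correlation), among them TP53INP1 (3.26 ± 0.08), ZMAT3 (0.87 ± 0.09) and RRM2B (0.85 ± 0.13). Of 15 genes of unfolded protein and amino acid stress 5 were lower and 2 higher, 6 and 3 adjusted over the list alone (adjusted p = 0.036; adjusted p = 0.52 with an estimated correlation). The cystine transporter gene SLC7A11 (−2.55 ± 0.11), asparagine synthetase ASNS (−2.52 ± 0.09) and ATF3 (−1.59 ± 0.15) were lower, and PDIA4 was higher by 1.16 ± 0.11. The adjusted p of this list was 0.054 after median centring, 0.089 without genes below the median level, and 0.087 or 0.066 without knockout replicate 1 or parental replicate 2 at 1% oxygen.

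**Figure D3:**
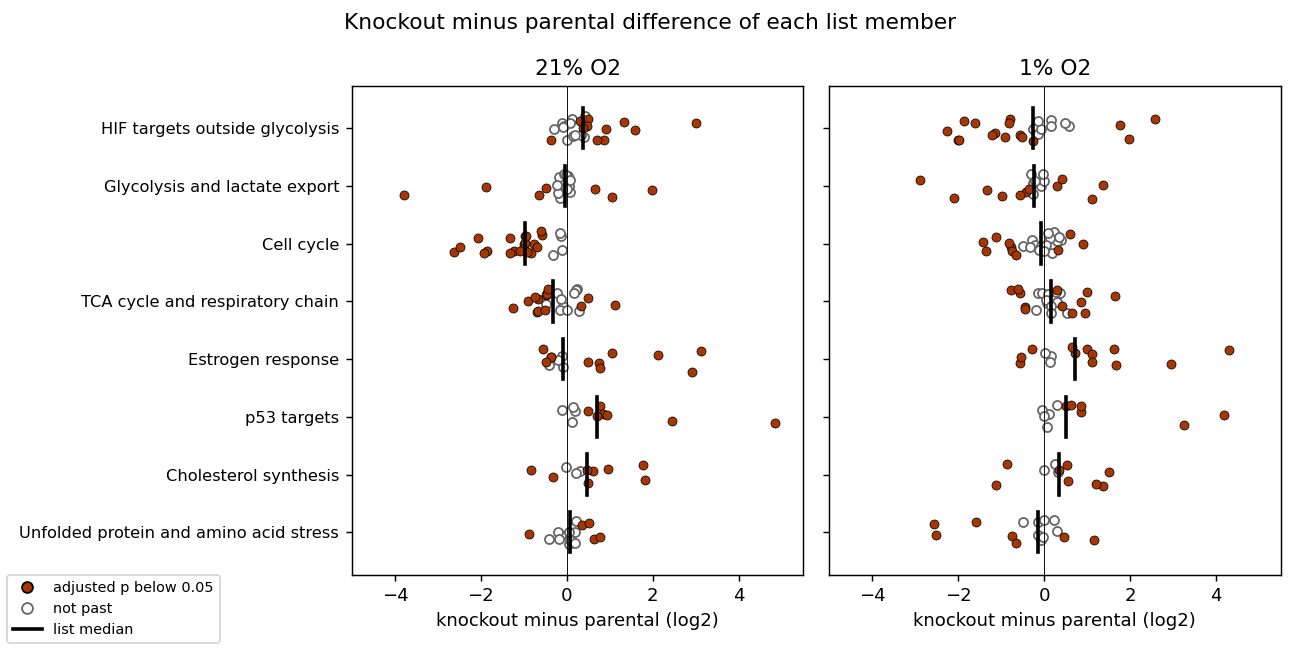
Knockout minus parental difference (log2, x axis) of each measured member of 8 gene lists at 21% O2 (left) and 1% O2 (right); filled points passed the adjusted threshold, open points did not, and bars are list medians. The cell cycle median lies at −0.97 at 21% O2 and −0.07 at 1% O2, and the median of HIF targets at 0.38 and −0.26.

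At 1% oxygen 4804 genes differed between the lines, 2897 higher and 1907 lower in the knockout line, with 682 and 430 over 2-fold. Lower genes made up 39.7% of the calls as deposited and 49.9% after quantile normalization, and 2979 genes passed when only the 2 groups compared were fitted.

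Whether the response to low oxygen differed between the lines was tested as the interaction. CLDN1, a tight junction gene, rose by 3.73 in parental cells and had a change of −0.81 in the knockout line, an interaction of −4.54 ± 0.14. TGFB2 (−3.94 ± 0.16), the glycoprotein hormone gene STC1 (−3.73 ± 0.31), MT1F (−3.37 ± 0.20), MMP13 (−3.22 ± 0.24), CYP1B1 (−2.97 ± 0.20), ANXA3 (−2.91 ± 0.13) and GADD45A (−2.84 ± 0.24) followed. At the other end, H1-4 had an interaction of 3.43 ± 0.42, RHOBTB3 of 3.18 ± 0.11, SCIN of 2.92 ± 0.13 and IGFBP5 of 2.5 ± 0.17. H2BC10, ATP9A, CHD4 and SLC6A6 had interactions of 2.43, 2.41, 2.38 and 2.38. H2BC10 had an adjusted p of 0.0335 and lost its call without 6 of the 8 arrays, with an interaction of 1.9 to 2.61 in those fits. MT1F and MMP13 lay near background in the knockout line at 21% oxygen (4.68 and 4.81), so the sizes and ranks of their interactions are uncertain.

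Of 25 HIF targets outside glycolysis 15 had a lower and 1 a higher response in the knockout line, 19 and 2 adjusted over the list alone, with a median interaction of −0.84. The adjusted p was 7.2e-15, or adjusted p = 0.077 with an estimated correlation. NDRG1 (−2.75 ± 0.16), KDM3A (−2.26 ± 0.18), BHLHE40 (−1.68 ± 0.14) and P4HA1 (−1.61 ± 0.12) were among the 15. Of 25 cell cycle genes 20 had a higher value, 22 adjusted over the list alone, with a median of 0.8 (adjusted p = 4.2e-14; adjusted p = 0.32 with an estimated correlation). TYMS (2 ± 0.20), MKI67 (1.36 ± 0.15), CCNA2 (1.2 ± 0.14) and RRM2 (1.01 ± 0.12) had the lowest p. The median line difference of the cell cycle list was −0.97 at 21% oxygen, itself a term of the interaction. At 1% oxygen it was −0.07 (camera adjusted p = 0.18), so the lines differed in this list mainly at 21% oxygen. Of 15 genes of unfolded protein and amino acid stress 7 were lower and 1 higher, 8 and 2 adjusted over the list alone (adjusted p = 1e-04; adjusted p = 0.32 with an estimated correlation). SLC7A11 (−2.35 ± 0.15), ATF3 (−1.64 ± 0.22), ASNS (−1.63 ± 0.12) and CHAC1 (−0.78 ± 0.11) were lower. CHAC1 lay at 4.40 to 5.04 in the 4 groups and ATF3 at 4.70 in parental cells at 21% oxygen, near background. Of 24 genes of the TCA cycle and respiratory chain 5 were higher, 9 adjusted over the list alone (adjusted p = 0.00015; adjusted p = 0.65 with an estimated correlation). IDH2 (1.54 ± 0.25), IDH3A (1.15 ± 0.16), ATP5F1A (0.74 ± 0.10) and NDUFA9 (0.49 ± 0.11) had the lowest p. The median of that list was 0.38, and 0.22 after quantile normalization, and its adjusted p was 0.05 without genes below the median level. With fry, which asks whether a list moved in 1 direction and not whether it moved against other genes, the adjusted p was 0.093. Its mixed version, which counts changes in either direction, gave an adjusted p of 0.004. NDUFA9 lost its call without 6 of the 8 arrays and under each other normalization, with an adjusted p of 0.318 after quantile normalization, and IDH2 of 0.0544 and 0.0533 without parental or knockout replicate 1 at 21% oxygen.

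In all, 2226 genes passed the interaction test, 1623 higher and 603 lower, with 490 and 186 over 2-fold. Of these, 1101 were called only in parental cells and 305 only in the knockout line, 610 moved the same way in both and further in parental cells, 86 further in the knockout line, 92 in opposite directions, and 32 were called in neither. Higher genes made up 72.9% of the calls as deposited, 52.6% after quantile normalization and 54.9% after cyclic loess normalization. Without 1 array, 901 or 850 (parental 21% oxygen), 1343 (parental 1% oxygen, replicate 1), 878 or 842 (knockout 21% oxygen) and 3522 genes (knockout 1% oxygen, replicate 1) passed, and 1161 rows passed when all rows of the table were tested.

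The HIF and PFKFB genes behind the question in the title ran as follows. EPAS1 was at 6.24 ± 0.13 (SD, n = 2) and 6.90 ± 0.30 (SD, n = 2) in parental cells at 21% and 1% oxygen, and at 10.61 ± 0.01 (SD, n = 2) and 10.28 ± 0.04 (SD, n = 2) in the knockout line. The line difference was 20.6-fold at 21% and 10.4-fold at 1% oxygen. The list of genes often assigned to HIF-2 did not pass between the lines (camera adjusted p = 0.35 at 21% and 0.55 at 1% oxygen). It did not pass in the interaction either (adjusted p = 0.47). Of its 13 measured genes, 3 were higher and 2 lower in the knockout line at 21% oxygen, and none differed at 1% oxygen. In response to 1% oxygen, 3 rose and 1 fell in parental cells, against 4 and 1 in the knockout line. EPAS1 rose by 0.66 ± 0.14 in parental cells (adjusted p = 0.0109; 0.0798 without parental replicate 2 at 21% oxygen) and had a change of −0.33 ± 0.14 in the knockout line (adjusted p = 0.164). Its interaction was −0.98 ± 0.20 (adjusted p = 0.0231), and lost its call without any one of the 4 arrays at 21% oxygen. HIF1A was at 13.14 and 10.59 in parental cells and at 15.66 and 11.41 in the knockout line, with an interaction of −1.69 ± 0.14.

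PFKFB3 rose 11.8-fold in parental cells (3.55 ± 0.17) and 5.96-fold in the knockout line (2.57 ± 0.17). At 21% oxygen its level did not differ detectably between the lines (−0.07 ± 0.17, adjusted p = 0.871), and at 1% oxygen it was 2.07-fold lower in the knockout line (−1.05 ± 0.17, adjusted p = 0.00466). The interaction was −0.98 ± 0.25 (adjusted p = 0.0506) and did not pass. PFKFB4 rose by 2.3 ± 0.10 and 2.2 ± 0.10 in the parental and knockout lines, and its interaction was −0.09 ± 0.14 (adjusted p = 0.774). PFKFB2 was higher in the knockout line by 0.54 ± 0.08 at 21% oxygen and 0.82 ± 0.08 at 1% oxygen. PFKFB1 passed in no comparison, but its mean levels of 3.79 to 3.95 lay below the median gene (4.71), near background, so its row can show little. Of the 5 genes of the PFKFB family and TIGAR 2 rose and 1 fell in each line, and the list passed in neither (adjusted p = 0.25 in both).

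PKM rose by 0.53 ± 0.15 in parental cells (adjusted p = 0.034) and by 1.42 ± 0.15 in the knockout line (adjusted p = 0.000922), with an interaction of 0.89 ± 0.21 (adjusted p = 0.0388). The parental rise had an adjusted p of 0.112 after median centring, and 0.12, 0.143 and 0.131 without either parental array at 21% oxygen or replicate 2 at 1% oxygen. The interaction lost its call without 6 of the 8 arrays, at 0.7 to 1.01. VEGFA rose by 1.9 ± 0.09 in the knockout line; its interaction was −0.51 ± 0.13 (adjusted p = 0.0466), with an adjusted p of 0.0714 with the replicate block and 0.0546 with a trend and robust prior, and it lost its call without 6 of the 8 arrays, at −0.43 to −0.52. VEGFA was higher in the knockout line at 21% oxygen by 0.38 ± 0.09 (adjusted p = 0.0207), with an adjusted p of 0.0997 to 0.119 without any one of the 4 arrays compared. SLC2A1 rose by 1.8 ± 0.12 in the knockout line and was lower there than in parental cells at 21% (−0.48 ± 0.12) and 1% oxygen (−0.56 ± 0.12). The first lost its call without any one of the 4 arrays compared, and the second had an adjusted p of 0.07 when only the 2 groups were fitted and 0.0502 and 0.0693 without parental replicate 1 or 2.

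The remaining lists are given by their adjusted p. In parental cells, genes often assigned to HIF-2 (0.038), mesenchymal and basal markers (0.012) and unfolded protein and amino acid stress (0.037) passed upward. Pentose phosphate and serine synthesis (0.043) and the splicing factors (0.043) passed downward, while interferon-stimulated genes (0.65), p53 targets (0.14) and epithelial genes (0.068) did not pass. In the knockout line, the TCA cycle and respiratory chain (3.6e-07) and epithelial genes (0.044) passed downward and mesenchymal markers (0.036) upward. Between the lines at 21% oxygen, cholesterol synthesis was higher (0.0062) and the TCA cycle and respiratory chain lower (0.019). None of these 10 calls held with an estimated correlation, where the adjusted p ran from 0.19 to 0.71. After quantile normalization, the calls for HIF-2 genes, mesenchymal markers, pentose phosphate genes and splicing factors in parental cells ended, as did epithelial and mesenchymal genes in the knockout line and the TCA cycle between the lines. Calls gained there were p53 targets in parental cells (0.00032), upward, and cholesterol synthesis between the lines at 1% oxygen (0.045), higher.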

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

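The tests of the share of falling genes and of HIF targets lower at 1% oxygen were chosen after the result was seen; the other tests were set before it.

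The response to 1% oxygen differed between the 2 lines by the interaction test in 2226 genes, 1623 of them with a higher and 603 with a lower value in the knockout line. Among lists, the median interaction was −0.84 for HIF targets outside glycolysis, 0.8 for the cell cycle, 0.38 for the TCA cycle and respiratory chain and −0.37 for unfolded protein and amino acid stress. Among genes followed throughout, PKM had an interaction of 0.89, HIF1A of −1.69, EPAS1 of −0.98 and VEGFA of −0.51. Of the 124 named genes, 86 passed this test.

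Genes named for the interaction had these values. The lowest were CLDN1 (−4.54), TGFB2 (−3.94), STC1 (−3.73), MT1F (−3.37), MMP13 (−3.22), CYP1B1 (−2.97), ANXA3 (−2.91), GADD45A (−2.84), NDRG1 (−2.75). Then came SLC7A11 (−2.35), KDM3A (−2.26), BHLHE40 (−1.68), ATF3 (−1.64), ASNS (−1.63), P4HA1 (−1.61), CHAC1 (−0.78). The highest were H1-4 (3.43), RHOBTB3 (3.18), SCIN (2.92), IGFBP5 (2.5), H2BC10 (2.43), ATP9A (2.41), SLC6A6 (2.38), CHD4 (2.38), TYMS (2). Above 0 were also IDH2 (1.54), MKI67 (1.36), CCNA2 (1.2), IDH3A (1.15), RRM2 (1.01), ATP5F1A (0.74), NDUFA9 (0.49).

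Genes named for another comparison also passed the interaction test. Lower in the knockout response were SERPINA3 (−2.64), BCAS1 (−2.38), HK2 (−2.11), DCDC2 (−1.97), PRKAA2 (−1.94), MBOAT1 (−1.92), PRSS23 (−1.92), BNIP3 (−1.88), MXI1 (−1.88), MSMO1 (−1.78). So were HIPK2 (−1.6), RET (−1.48), POFUT4 (−1.47), ALDOC (−1.28), PREX1 (−1.27), HMGCS1 (−1.26), PDK1 (−1.09), STC2 (−1.03), VLDLR (−0.95), ERRFI1 (−0.92). The rest below 0 were CITED2 (−0.92), PGK1 (−0.86), LOXL2 (−0.73), BNIP3L (−0.64), CYP51A1 (−0.54). Higher in the knockout response were ANP32E (1.7), ESR1 (1.57), FAM72D (1.39), XBP1 (1.38), H2BC14 (1.37), NPY1R (1.28), PGR (1.21), ANXA9 (1.16), SLC11A2 (1.15), MCM7 (1.13). To these belong HNRNPA2B1 (1.12), PLXDC2 (1.06), PLIN2 (0.95), PDIA4 (0.95), NRIP1 (0.92), LSS (0.91), ODC1 (0.81), TP53INP1 (0.81), ARRDC3 (0.78), CCNB1 (0.73). The rest above 0 were MCM6 (0.73), PLK1 (0.67), PRKD3 (0.54), HMCN1 (0.54), SRSF3 (0.43). HMCN1, PRKAA2, MT1F, MMP13, ATF3 and CHAC1 lay near background in at least 1 group, so the sizes of their interactions are uncertain.

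Some genes named in a caption or among the other observations were picked after their values had been seen and are not among the 124. Those that passed the interaction test were H2BC17 (1.8), LOX (1.69), H2AC21 (1.66), H2AC12 (1.16) and MT1X (1.01). MT1X had a limma adjusted p of 0.0481, and its call ended after quantile and after cyclic loess normalization. LOX lay below the median gene in both lines at 21% oxygen (4.08 and 4.16).

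Among the 45117 rows outside the 22411 genes, most of them without a symbol, a signal above the arrays at 21% oxygen was also seen. Of these rows 343 rose over 2-fold at 1% oxygen in parental cells and 273 in the knockout line, and more fell over 2-fold, 1042 and 351.

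More genes fell than rose in parental cells at 1% oxygen (63.6% of calls). The arrays at 1% oxygen had a narrower signal range, but the median change by level was not an even narrowing: 0.14 below a level of 4, −0.33 at 10 to 12 and −0.15 above 12. After cyclic loess normalization 54% of calls fell, and after quantile normalization 53.5%. These shares do not decide it, because both normalizations bring the distributions of the arrays together and pull the shares that fell and rose together whatever the cause. The narrower range and a response of the cells to 1% oxygen cannot be told apart here, since every array at 1% oxygen has that range.

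HIF targets outside glycolysis rose less in the knockout line, with a median interaction of −0.84. The narrower signal range is argued against, since after quantile normalization the median was −0.94 and the list still passed (as deposited, adjusted p = 0.077 with an estimated correlation). A higher starting level may contribute, because the list's median was 0.38 higher in the knockout line at 21% oxygen. That difference is also a term of the interaction, from the same arrays, so it is not separate support. The 13 members that ended below parental cells at 1% oxygen do not decide it, since they were picked for being lower. Over the whole list the median difference at 1% oxygen was −0.26, with 13 lower and 3 higher (camera adjusted p = 0.00023, or 0.32 with an estimated correlation). A higher start alone would not place the list below parental cells, so at the preset correlation this argues against it as the whole account. Loss of PKM2, named by the design, stays open and untested, and so do other differences between the lines.

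Between the knockout and parental lines 4713 genes differed at 21% oxygen. Another cell line in place of the knockout is argued against by MTAP, deleted in MCF7, which differed by 0.1 and lay below the median gene (4.71) in both lines at 21% oxygen; at 1% oxygen it was at 4.65 in parental cells and 4.86 in the knockout line. A line that also lacks MTAP would escape this test. Copy number differences may account for part of it: medians over windows of 25 neighbouring expressed genes spread 2.84 times as widely as with gene order shuffled, against 1.22 times for the parental oxygen response. EPAS1 is not part of a wide gain, since the median difference of its 24 expressed neighbours was −0.48, while a gain of EPAS1 alone would escape this test. Other named genes were not compared with their neighbours in this way. CAV1 and SLC7A11 lay in windows with medians of −0.67 and −0.76 at 21% oxygen, and −0.68 and −0.55 at 1% oxygen.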

How the results depend on the processing

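The setting with cyclic loess normalization was chosen after the data had been seen. Across settings, 63 of the values of named genes lost their call, 11 gained one and 11 changed direction, against 3121 that stayed on their side; for lists these were 86, 34, 37 and 1107. The list calls for HIF targets outside glycolysis in both oxygen responses held in each setting run. The cause of the changes below was not tested unless the setting itself gives it (fewer genes, fewer arrays or a stricter threshold). Signal near background limits what low genes can show; no detection call was used.

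The replicate numbers did not pair the arrays: differences between replicate 1 and 2 correlated by −0.059 to 0.092 between groups. With a replicate block 6172, 3454, 4591, 4636 and 2080 genes passed in the parental response, knockout response, line difference at 21% and at 1% oxygen and the interaction, none over 1.5 times from the main count, and the overlap was 671 and 1647.

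With a 2-fold threshold added to the adjusted p, 1567, 592, 1092, 1112 and 676 genes passed in that order, and with an unadjusted p 1573, 606, 1097, 1123 and 754, with an overlap of 143 rising and 219 falling. Fitting only the 2 groups gave 2351 in the knockout response and 2979 between the lines at 1% oxygen. All rows gave 1161 for the interaction. The overlap that rose was 1102 after quantile normalization, 1097 after cyclic loess normalization and 398 after median centring; the overlap that fell was 2864 after median centring. The percent of calls that fell, as deposited and after quantile, median centring and cyclic loess, was 63.6, 53.5, 83.5 and 54 (parental response), 60.2, 54.4, 81.6 and 54.3 (knockout response), 39.7, 49.9, 42.5 and 48.1 (lines at 1% oxygen) and 27.1, 47.4, 25.3 and 45.1 (interaction). After quantile normalization 4458 of 6480, 3060 of 3588, 4306 of 4713, 4394 of 4804 and 1681 of 2226 calls were kept, none in the opposite direction. Quantile and cyclic loess normalization pull the percent that fell towards 50 by themselves. Without replicate 1 of the knockout line at 1% oxygen, 41.4% of calls fell in the knockout response.

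Of the lists, 11, 9, 6, 5 and 4 passed in the 5 comparisons. An estimated correlation left 1, 1, 0, 0 and 0, quantile normalization 5 in the knockout response, the filter on low genes 3 and fry, which tests against no change and not against other genes, 9 between the lines at 1% oxygen. Leaving out 1 array gave 4075 to 7611, 1679 to 4830, 3046 to 5362, 3673 to 5729 and 842 to 3522 genes, 8 to 12, 6 to 10, 6 to 6, 3 to 7 and 4 to 6 lists, and overlaps of 379 to 1101 and 871 to 1861. A group left with 1 array was assumed to vary like the others.

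Directions changed only in values that had not passed. In the knockout response, PFKFB2 (0.04) was −0.11 after median centring and −0.05 to 0.13 without 1 array. PFKFB3 between the lines at 21% oxygen (−0.07) was 0.05 after cyclic loess. PFKFB4 between the lines at 1% oxygen (0.01) was −0.12, −0.02 and −0.1 after quantile, median centring and cyclic loess, and −0.14 to 0.15 without 1 array. Without 1 array, PFKFB1 between the lines at 1% oxygen was −0.1 to 0.04, and the interactions of PFKFB4 and SLC2A1 −0.24 to 0.05 and −0.26 to 0.11. For lists, the value is the mean shift against other genes, and a change counts if that shift or the direction of the test turned. Interferon-stimulated genes were at −0.28, −0.1 and −0.09 (low genes left out, quantile, cyclic loess) in the parental response, with −0.01 to 0.05 without 1 array, at 0 and 0 (quantile, cyclic loess) in the knockout response, and at 0.01 and 0.01 between the lines at 21% oxygen. Without 1 array they were at 0.06 to 0.12 between the lines at 1% oxygen and 0.01 to 0.07 in the interaction. HIF subunits in the knockout response were at 0.28, 0.29, 0.18 and 0.27 (low genes left out, quantile, median centring, cyclic loess) and 0.12 to 0.24 without 1 array; there the median (−0.04) and mean (0.2) differ in sign. Glycolysis between the lines at 21% oxygen was at −0.1 after cyclic loess. Between the lines at 1% oxygen, the PFKFB family was at −0.11 to 0.06, mesenchymal markers at 0 to 0.07 and 0.03 with fry, and pentose phosphate genes at −0.21 to 0.01. In the interaction, epithelial genes were at 0.09 (replicate block), 0 (low genes left out), 0.09 (median centring), 0.09 (fry) and 0 to 0.17 without 1 array, mesenchymal markers at 0.22 (low genes left out) and 0.01 (quantile), pentose phosphate genes at 0 (quantile) and HIF-2 genes at −0.09 (fry).

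Median, mean and test also differed in sign for estrogen response genes between the lines at 21% oxygen (median −0.1, mean 0.57), for unfolded protein and amino acid stress in the knockout response (0.05 and −0.19), and between the lines at 1% oxygen for pentose phosphate genes (0.11 and −0.05) and mesenchymal markers (−0.01 and 0.08).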

Other observations

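The groups in this part and the genes named from them were chosen after the data had been seen. Of 32 clustered histone genes, whose transcripts are made mostly during DNA replication, 26 fell and 1 rose in parental cells at 1% oxygen, with a median of −1.52. In the knockout line 17 fell and none rose, with a median of −0.66. At 21% oxygen 12 were lower and 4 higher in the knockout line, while at 1% oxygen 8 were higher and none lower. The interaction was higher for 15 and lower for 1. H2BC17 (−3.03 ± 0.11), H2AC21 (−2.72 ± 0.17) and H2AC12 (−2.3 ± 0.11) are further examples from parental cells. After quantile normalization the parental median was −1.4, after median centring −1.66 and after cyclic loess −1.36. Members of this family may share probes, which was not tested, so their separate values are uncertain.

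Metallothioneins, which bind zinc and copper, rose in parental cells for 8 of 11 measured genes and in the knockout line for 5. MT2A rose by 2.89 ± 0.26 and 2.14 ± 0.26, and MT1X by 2.8 ± 0.18 and 3.8 ± 0.18. MT1F rose by 4.08 ± 0.14 and 0.71 ± 0.14, the latter from a level near background (4.68). At 21% oxygen 5 were lower in the knockout line and none higher, with a median of −0.4. At 1% oxygen 7 were lower and none higher, with a median of −0.87, against −1 after quantile normalization and −0.9 after the other normalizations. Sharing of probes within this family was not tested, and some members lay near background. As deposited, 2 members had a lower and 1 a higher interaction. The higher call, MT1X, ended after quantile and after cyclic loess normalization.

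At 21% oxygen the window medians of the line difference lay furthest from 0 on chromosome 17, followed by chromosomes 1, 7 and 2. The 25 expressed genes on chromosome 17 from BRIP1 to GNA13 had a median difference of 1.18 at 21% oxygen, and 1.52 at 1% oxygen. The next 25, from PRKCA to MRPL58, were at 1.17 and 1.09. On chromosome 1, genes from OTUD7B to ZNF687 were at −1.09 and −0.65, on chromosome 7 those from TMEM60 to PEG10 at −1.05 and −0.83, and on chromosome 2 those from ADCY3 to SLC4A1AP at −1.01 and −0.8. The parental oxygen response of the 5 windows was −0.3, −0.15, −0.38, −0.08 and −0.52. Every window on chromosome X had a higher median in the knockout line, from 0.3 to 0.81 at 21% oxygen and from 0.6 to 1.03 at 1% oxygen. The line differences at the 2 oxygen levels come from separate arrays and shared 1334 higher and 1147 lower genes, against 262 and 228.6 for independent lists.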
